A study of Mus musculus with 87 samples.

How the data were processed

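Affymetrix MG_U74Av2 arrays measured RNA from 6 brain regions and the pituitary gland of 6 inbred mouse strains (87 arrays, 42 groups of strain and region, 8-week-old males). Per the labels, RNA was extracted with Trizol from tissue kept in RNALater, and 1 to 5 mice were pooled per array. RNA of the amygdala and the cingulate cortex was amplified from 50 ng by making cDNA and transcribing it in 2 rounds, and RNA of the other regions was labelled in 1 round from 10 µg. The authors deposited a matrix of values in the unit intensity, with background subtracted, and an experiment file for each array. The software that made the values and their scaling are not given in the sources used here.

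The deposited intensity values are on a linear scale, and 6.33% of them lie below 0. The log2 medians of the arrays ranged from 5.87 to 6.36, a range of 0.487, so the values were used as deposited under a rule that allowed a range of 0.5. Values below 0 were set to 0 and log2(intensity + 16) was taken. All log2 differences and folds are on this scale, so folds against a group near background depend on the 16 and understate the ratio of the raw intensities. Group intensities named in the text are means on this scale transformed back, and the mean ± SD of Glo1 and Gsr are of intensities.

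Of 12488 probe sets, 66 controls were left out. A probe set was tested if its highest group mean exceeded the median of all values (intensity 55.4), which left 8460 of 12422. Gene symbols came from the annotation table of the array, and 10817 were brought up to date by gene identifier from a table of RefSeq gene names (assembly GRCm38.p6). A single symbol was assigned to 10833 probe sets (7631 tested), several symbols to 396 (270 tested) and none to 1193 (559 tested). Only probe sets with 1 symbol were named or entered in gene lists. The tested probe sets stand for 6315 genes, of which 1134 have more than 1 probe set.

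Differences were tested with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, statmod 1.5.0), with a mean for each of the 42 groups and moderated variances. Each strain was compared with the mean of the other 5 strains, averaged over the 7 regions with equal weight. F tests asked whether a probe set differed among strains over all regions, within each region, and whether strain differences depended on the region (interaction). The bed nucleus, hippocampus, hypothalamus and periaqueductal gray were each compared with the mean of the other 3, and the pituitary gland with the mean of these 4. The amygdala was compared with the cingulate cortex. No comparison of regions crosses the labelling protocols in the fit reported. P-values were adjusted by Benjamini and Hochberg over all probe sets tested. A probe set was called in a comparison at adjusted p below 0.05 and a difference of at least 2-fold, and in an F test at adjusted p below 0.05. Errors of log2 differences are standard errors (SE) from limma.

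Gene lists were tested with camera in limma with a preset correlation of 0.01, and again with camera with an estimated correlation and with fry, each adjusted over 312 tests (26 lists, 12 comparisons). Pre-ranked camera (cameraPR, on the moderated t statistics, preset correlation) was run with and without the scan day block. A gene with several probe sets entered by the one with the highest mean, and a list symbol was matched to a synonym only where it is not the symbol of another gene. Counts of list members use adjusted p below 0.05 with no fold minimum, over all genes and adjusted over the list alone. The lists held genes of the hippocampus, hypothalamus, midbrain, subpallium, pituitary gland, cortical glutamatergic neurons and amygdala. Lists of cell types held genes of GABA interneurons, myelin, astrocytes, microglia, endothelium, choroid plexus, meninges, ependyma and blood. The others held immediate early, glyoxalase and antioxidant, histocompatibility, strain variant, GABA-A receptor, glutamate receptor, stress and corticotropin-releasing hormone, monoamine, ribosomal and mitochondrial genes. Of the 312 tests 86 were called with the preset correlation.

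Genes were named by a rule. Each strain comparison names the 4 highest and 4 lowest genes among probe sets with adjusted p below 0.05 and the same sign in all 7 regions. Each of the 4 brain regions names its 10 highest genes, the pituitary gland its 12 highest and 6 lowest, and the amygdala its 8 highest and 8 lowest, with the same sign in all 6 strains. The interaction names the 10 genes with the largest F. Lists name up to 4 members with the largest absolute difference. Glo1, Gsr and the strain variant genes were named whatever their values. The groups, comparisons, tests, naming rule, lists and most alternatives were chosen before the data were examined.

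The fits were tested on simulated data, in which 100 of the 8460 probe sets were changed at each of 2 sizes, and recovered means adjusted p below 0.05 with no fold minimum. A change of 1.5-fold was recovered for 99 in the A/J comparison, 97 in the hippocampus, 98 in the pituitary gland and 94 in the amygdala, with 8 to 20 other probe sets called. The interaction recovered 0 at 1.5-fold and 69 at 2.83-fold, and strain differences within the hippocampus 3 and 81. Strain differences of 1.5-fold within the hippocampus were thus mostly missed. Of 200 unchanged lists of 20 genes 0 were called. The simulated noise was independent between probe sets and arrays. False calls from correlated genes, shared scan days or shared animals were therefore not tested.

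The strain profile of an array was its correlation, over 200 probe sets chosen in the other regions, with the mean profile of each strain. The experiment files list 17 scan days, 8 chip lots, 92 animals and 23 cages, and 26 arrays scanned 1 time and 61 scanned 2 times. In 28 groups all arrays were scanned on 1 day. For 85 arrays the animals named match the number pooled, and for 2 arrays the file names no strain. Replicate pairs scanned on the same day differed less: the median SD of the difference was 0.288 against 0.367 in 1 round (22 and 10 pairs), and 0.390 against 0.472 in 2 rounds (7 and 9 pairs).

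Alternatives tried were 3 other scalings, pseudocounts of 1 and 64, other level filters, other fold minima, a trended robust prior, array weights, blocks by replicate number and scan day, subsets of regions, 1 probe set per gene and leaving out each array or replicate. Blocks by cage and chip lot, the number of scans as a term, fits within the arrays of 1 or 2 scans, additive fits and a fit without the 4 pituitary arrays were added after seeing the data. The raw image files were not analysed here, and all columns of the deposited table were used.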

Results

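Gene expression was measured in male mice, 8 weeks of age, of 6 inbred strains: 129S6/SvEvTac, A/J, C57BL/6J, C3H/HeJ, DBA/2J and FVB/NJ. The tissues were the amygdala, bed nucleus of the stria terminalis, cingulate cortex, hippocampus, hypothalamus, periaqueductal gray (a midbrain region) and pituitary gland. Each of the 87 arrays held RNA of 1 to 5 mice of one strain and tissue. Of the 42 groups of strain and tissue, 39 had 2 arrays and 3 had 3 arrays. RNA of the amygdala and the cingulate cortex (26 arrays) was amplified in 2 rounds from 50 ng, and all other RNA (61 arrays) in 1 round from 10 µg. Median intensity of an array ranged from 42.3 to 66.1 and the upper quartile from 164 to 185, and these arrays measured 8460 probe sets above the level needed for a test. Replicate arrays correlated at 0.946 to 0.991 over 48 pairs.

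Animals were shared between tissues, so the arrays are not all independent: 81 arrays name an animal that also gave an array of another region. A further overlap is that 4 arrays name the same animal as a replicate of their own group, and no 2 arrays held identical values. All p-values measure only the spread between these samples, part of which may be technical. Signal at the 5' end of transcripts was lower in RNA amplified in 2 rounds. The log2 ratio of the 3' to the 5' probe set of Gapdh was 2.71 ± 0.36 (SD, n = 26) after 2 rounds and -0.07 ± 0.12 (SD, n = 61) after 1 round, and that of beta-actin was 2.89 ± 0.30 and 0.81 ± 0.14. Regions were compared only within a protocol.

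**Figure D1:**
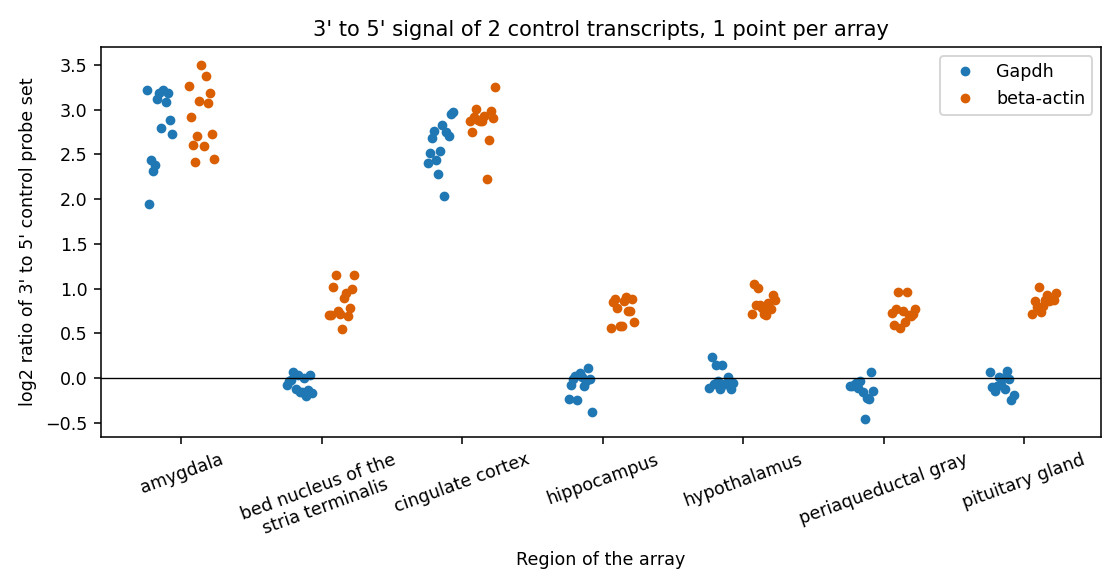
Log2 ratio of the 3' to the 5' control probe set of Gapdh and beta-actin (vertical axis) in each region (horizontal axis). Each point is 1 array.

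The strain label of 83 of the 87 arrays matched the strain whose expression profile the array carried, and the label of 4 pituitary arrays did not. Profiles were built from 200 probe sets chosen in the other 6 regions. The 83 arrays correlated at 0.746 to 0.948 with their own strain and at most at 0.110 with another. The arrays labelled C3H/HeJ and FVB/NJ in the pituitary gland correlated at -0.321 to -0.283 with their label and at 0.841 to 0.888 with the profile of each other's strain. All comparisons below keep the labels as given, and comparisons of the strains C3H/HeJ and FVB/NJ are affected by this.

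**Figure D2:**
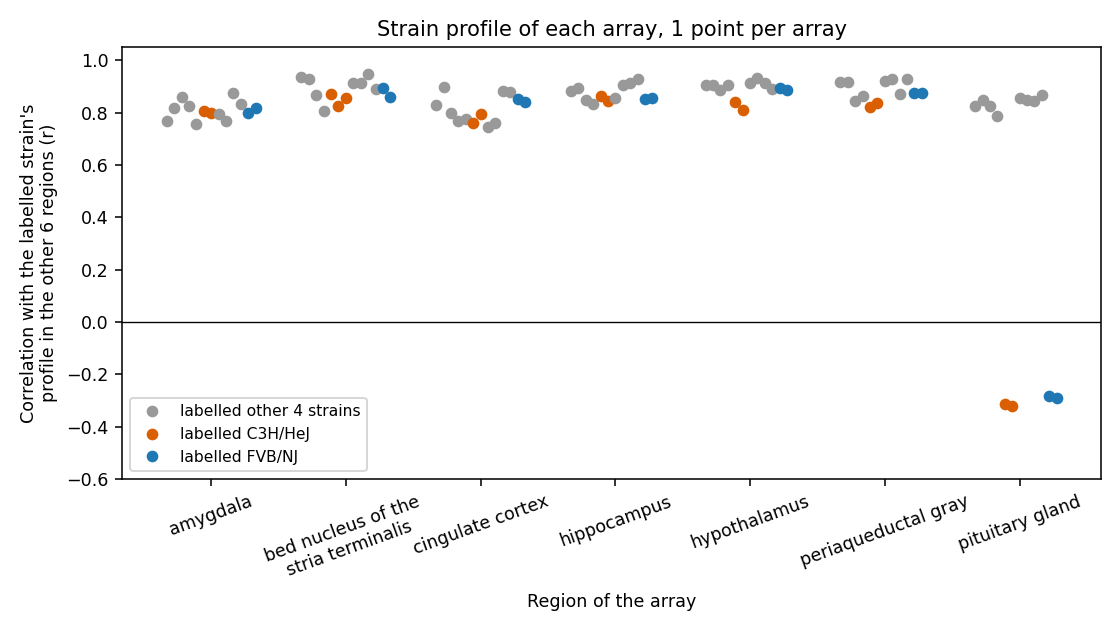
Correlation of each array with the profile of its labelled strain (vertical axis) by region (horizontal axis). Each point is 1 array, and the profile was built from the other regions.

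Strain differences in Glo1 were large and held through most tissues. Glo1 encodes glyoxalase 1, which detoxifies methylglyoxal. Its mean intensity was highest in A/J (1603 ± 346, SD, n = 15) and lowest in C57BL/6J (541 ± 138, n = 14), while without the pituitary gland FVB/NJ was lowest (545 ± 109 against 580 ± 106 in C57BL/6J, n = 12 each). Between them lay 129S6/SvEvTac (1153 ± 308, n = 15), DBA/2J (1128 ± 340, n = 14), C3H/HeJ (1035 ± 355, n = 15) and FVB/NJ (567 ± 114, n = 14). Against the mean of the other 5 strains the log2 difference was 0.93 ± 0.03 (SE) in A/J (adjusted p = 1.41e-28) and -0.90 ± 0.03 in C57BL/6J (adjusted p = 2.87e-28), each with the same sign in 7 of 7 regions. The difference was -0.80 in FVB/NJ, 0.34 in 129S6/SvEvTac, 0.32 in DBA/2J and 0.11 in C3H/HeJ (adjusted p = 0.0226), and a second Glo1 probe set gave 0.78 in A/J and -0.74 in C57BL/6J. The pituitary arrays labelled C3H/HeJ and FVB/NJ were the exception, at 377 ± 34.6 and 696 ± 0.42 (SD, n = 2 each). The C3H/HeJ value of Glo1 did not pass the test under the other scalings tried. Among arrays scanned 1 time it was -0.0169 (adjusted p = 0.984). No C57BL/6J array was scanned 1 time, so that fit lacks a strain low in Glo1. Its value cannot be set against the 0.11 above.

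**Figure D3:**
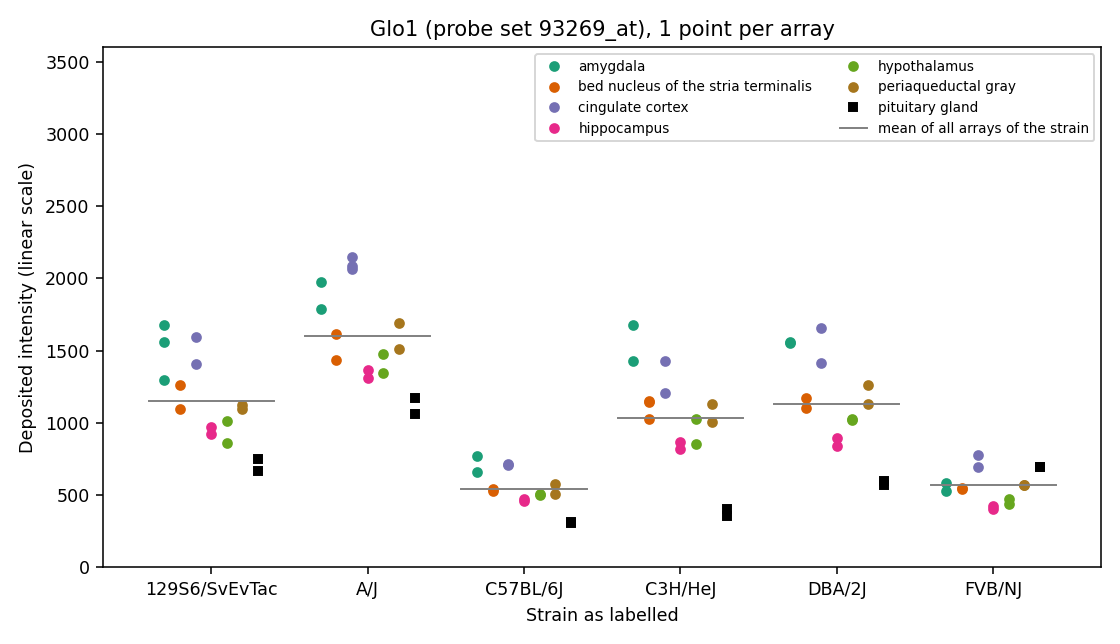
Intensity of Glo1 (vertical axis) in each array, grouped by labelled strain (horizontal axis) and coloured by region. Grey lines are the mean of each strain.

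Gsr, which encodes glutathione reductase, differed less. Mean intensity ran from 143 ± 52.1 in DBA/2J (SD, n = 14) to 73.4 ± 19.2 in C57BL/6J (n = 14). It was lower in C57BL/6J (log2 difference -0.55, adjusted p = 1.78e-07) and FVB/NJ (-0.27, adjusted p = 0.018) and higher in DBA/2J (0.40, adjusted p = 1.32e-04). In A/J, 129S6/SvEvTac and C3H/HeJ the Gsr values of 0.13, 0.14 and 0.15 were not different from the other strains (adjusted p = 0.285, 0.244 and 0.273). The FVB/NJ call for Gsr was lost with the scan day as a block (adjusted p = 0.167).

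Across all tissues 3189 of 8460 probe sets (37.7%) differed among the strains, and 1856 did with the scan day as a block. With the 42 group means as samples the count was 1214, and a scan day term gave 1623. The group means of a strain still share animals between regions, so neither fit removes that overlap. Without replicate 1 of each group 256 passed. Most differences were small: 120 calls in 81 probe sets reached 2-fold against the mean of the other 5 strains. By the naming rule all genes named below for single strains had the same sign in 7 of 7 regions. Their adjusted p ran from 1.36e-38 to 2.02e-09. The strain comparisons share arrays, so a gene high in some strains reads lower in the rest. Pam was at 402 in 129S6/SvEvTac and 375 in DBA/2J. It was at 28.6 in C57BL/6J, 31.9 in A/J, 34.7 in C3H/HeJ and 36.3 in FVB/NJ, and was named as lower in each of these. For C3H/HeJ and FVB/NJ the rule includes the pituitary arrays that carry the other strain's profile. It thus leaves out genes such as Pdxdc1 in C3H/HeJ (2.88 without the pituitary gland) and Capzb in FVB/NJ (-2.23). The rule also favours genes that differ the same way in both strains, and Pam, Tbc1d15 and Hat1 were named in both. Of 17 genes called at 2-fold that have another tested probe set designed on another sequence, 13 had the same sign in that probe set in the strain of their largest difference, and 12 in every strain where they were called. Pdxdc1 did not: its probe sets read in opposite directions in each strain where it is named.

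In 129S6/SvEvTac (15 arrays against 72) 7 probe sets were at least 2-fold higher and 19 lower. The largest increase was in Pam, which encodes the enzyme that amidates neuropeptides, at 402 against 58.0 (5.64-fold, log2 difference 2.50 ± 0.11, SE). Serpina3n, a serine protease inhibitor induced in reactive astrocytes, was 2.69-fold higher (1.43 ± 0.06), and Gdpd3 (1.25 ± 0.06) and Fxyd2, a regulatory subunit of the sodium pump (1.24 ± 0.10), were also higher. Gas5, a host gene of small nucleolar RNAs, was 3.03-fold lower (-1.60 ± 0.05), with another probe set at -0.64. Lower too were Arcn1 of the COPI vesicle coat (-1.55 ± 0.06), the complement inhibitor Cd59a (-1.53 ± 0.07) and Pdxdc1 (-1.53 ± 0.07). Without a fold minimum 740 probe sets were higher and 695 lower.

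A/J (15 arrays against 72) had 4 probe sets at least 2-fold higher and 11 lower. Mtm1, the phosphoinositide phosphatase of myotubular myopathy, was 3.92-fold higher at 458 against 105 (1.97 ± 0.05). Itgb1bp1 (1.27 ± 0.06), the dystrophin-complex gene Sspn (1.15 ± 0.06) and the class I gene H2-D1 (1.07 ± 0.07) were higher as well. Another probe set of Mtm1 read only 0.20, and those of Itgb1bp1 0.21 and 0.25. Pdxdc1 (-1.57 ± 0.07), Pam (-1.25 ± 0.11), Clip4 (-1.15 ± 0.10) and Gas5 (-1.14 ± 0.05) were lower in A/J. The other 2 H2-D1 probe sets read -0.16 and 0.21 and both passed the test, so they disagree in direction and only 1 probe set reached 2-fold.

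C57BL/6J (14 arrays against 73) had 14 probe sets higher and 9 lower. Snhg6, a host gene of small nucleolar RNAs, was 5.96-fold higher at 302 against 37.3 (2.58 ± 0.06). Among the genes named for single strains only Pdxdc1 had a larger difference. Prdx2, a peroxide-reducing enzyme, was 4.49-fold higher (2.17 ± 0.05), a probe set annotated to the locus Mir686 4.12-fold (2.04 ± 0.05; the mature microRNA was not measured), and Pttg1 or securin, which holds sister chromatids together, had a difference of 1.61 ± 0.09. Gnb1, a G protein beta subunit, was 4.07-fold lower at 55.4 against 275 (-2.03 ± 0.06), and the other 2 Gnb1 probe sets read -1.40 and -1.24. Pam (-1.37 ± 0.11), Pdxdc1 (-1.31 ± 0.08) and the chemokine receptor gene Ccr6 (-1.02 ± 0.08) were lower. Another probe set of Prdx2 read -0.18 and passed the test in the opposite direction.

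Arrays labelled C3H/HeJ (15 against 72) had 3 probe sets higher and 10 lower by 2-fold. Tbc1d15 (0.84 ± 0.07), the heme transporter gene Slc48a1 (0.60 ± 0.07), the initiator caspase gene Casp9 (0.57 ± 0.05) and Fgfr1op2 (0.55 ± 0.06) were higher. Pam (-1.15 ± 0.11), Sspn (-1.06 ± 0.06), the Y-box protein gene Ybx1 (-0.96 ± 0.04) and the histone acetyltransferase gene Hat1 (-0.94 ± 0.10) were lower. Second probe sets of Tbc1d15 and Hat1 read only 0.01 and -0.04 in C3H/HeJ. Without the pituitary gland the count was 18 in place of 13.

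DBA/2J (14 arrays against 73) had 12 probe sets higher and 13 lower. A Pdxdc1 probe set was 7.75-fold higher at 363 against 33.0 (2.95 ± 0.08), while the 2 other Pdxdc1 probe sets read -1.67 and -1.89. Pam was 5.22-fold higher (2.38 ± 0.11), with H2-D1 (1.48 ± 0.07) and the aspartic protease gene Ctse (1.25 ± 0.05). Other H2-D1 probe sets read 0.02 and 0.93. Cpsf2, part of the complex that cuts pre-mRNA before polyadenylation, was 3.67-fold lower (-1.88 ± 0.06), with another probe set at -0.40. The proteasome subunit gene Psmb6 (-1.57 ± 0.07) and Aldh9a1, an aldehyde dehydrogenase (-1.50 ± 0.07), were lower as well.

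Arrays labelled FVB/NJ (14 against 73) had 8 probe sets higher and 10 lower. Cd59a (1.13 ± 0.07), Tbc1d15 (0.91 ± 0.08), the lysosomal lipase gene Lipa (0.88 ± 0.09) and Padi2, which converts arginine to citrulline in myelin basic protein (0.76 ± 0.08), were higher. Pam (-1.10 ± 0.11), Hat1 (-1.08 ± 0.10), 6430706D22Rik (-0.99 ± 0.05) and the RNase P subunit gene Rpp14 (-0.84 ± 0.07) were lower. Second probe sets of Tbc1d15, Hat1 and Rpp14 read -0.05, 0.02 and 0.06, against the direction named. Without the pituitary gland the FVB/NJ count was 30 in place of 18.

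Genes with known strain variants followed the strain in 3 of the 4 that could be tested. Nnt, a mitochondrial transhydrogenase with a deletion in C57BL/6J, was lower in that strain (-0.74, adjusted p = 1.7e-16). Gabra2, a GABA-A receptor subunit, was also lower in C57BL/6J (-0.59, adjusted p = 1.96e-09). Myo5a, disrupted by the dilute insertion, was lower in DBA/2J (-0.63, adjusted p = 1.42e-07). Ahr passed the test in no strain, and Pde6b, Hc, Klrd1 and Tyr lay below the level tested. The list of strain variants as a whole was called lower in C57BL/6J, with 1 of 4 genes higher and 2 lower (1 and 2 adjusted over the list alone; median -0.33, adjusted p = 0.0212). That call was lost with an estimated correlation (adjusted p = 0.119 with an estimated correlation).

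Lists of microglia or histocompatibility genes were called in 3 strains. Each gene entered by 1 probe set, and whether a sequence variant under a probe made a list differ between strains was not tested. The H2-D1 probe sets disagreed in direction in A/J, and those of H2-K1 read -1.07 and -0.48 in C3H/HeJ. Of 11 microglia genes 4 were higher in C57BL/6J and none lower (6 and 1 adjusted over the list alone; median 0.16, adjusted p = 8.69e-04), among them the complement genes C1qc (0.77 ± 0.09) and C1qa (0.39). The 18 genes of the class I and II histocompatibility list had 5 members lower in C3H/HeJ and none higher (8 adjusted over the list alone; median -0.12, adjusted p = 8.44e-07), among them H2-D1 (-0.61 ± 0.05), H2-Q4 (-0.55) and H2-K1 (-0.48). In C57BL/6J 4 of them were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0158 and adjusted p = 0.189 with an estimated correlation), with B2m at 0.75 ± 0.05. Microglia genes were lower in C3H/HeJ (3 of 11, 4 adjusted over the list alone; adjusted p = 0.00834 and adjusted p = 0.0813 with an estimated correlation) and in 129S6/SvEvTac (1 higher and 3 lower, 1 and 4 adjusted over the list alone; adjusted p = 0.0166 and adjusted p = 0.119 with an estimated correlation).

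The remaining strain lists lost their calls with an estimated correlation. Myelin genes were higher in C57BL/6J (6 of 9, 7 adjusted over the list alone; median 0.33, adjusted p = 5.96e-04 and adjusted p = 0.199 with an estimated correlation), led by Mag (0.64 ± 0.11). In A/J the mitochondrial genes were higher (8 of 27, 13 adjusted over the list alone; median 0.09, adjusted p = 0.00142 and adjusted p = 0.282 with an estimated correlation). Immediate early genes were lower in A/J (4 of 16, 4 adjusted over the list alone; median -0.15, adjusted p = 0.00393 and adjusted p = 0.309 with an estimated correlation), with Fos at -0.70 ± 0.19 and Dusp6 at -0.35. In FVB/NJ, meningeal genes were higher (3 of 14, 7 adjusted over the list alone; median 0.24, adjusted p = 0.00211 and adjusted p = 0.311 with an estimated correlation), as were blood genes (2 of 4, 2 adjusted over the list alone; adjusted p = 0.0199 and adjusted p = 0.189 with an estimated correlation), with Hba-a1 at 0.70 ± 0.11. Midbrain genes (2 of 14, 2 adjusted over the list alone; adjusted p = 0.036 and adjusted p = 0.292 with an estimated correlation) were called there too. Myelin genes were lower in C3H/HeJ (2 of 9, 2 adjusted over the list alone; adjusted p = 0.0337 and adjusted p = 0.462 with an estimated correlation) and in DBA/2J (2 of 9, 3 adjusted over the list alone; adjusted p = 0.034 and adjusted p = 0.462 with an estimated correlation). The 29 glyoxalase and antioxidant genes were called in no strain by camera with the preset correlation, although pre-ranked camera called them higher in A/J (adjusted p = 0.0124). In A/J 4 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0791) and in C57BL/6J 4 were higher and 6 lower (4 and 7 adjusted over the list alone; adjusted p = 0.201).

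Strain effects on some genes depended on the region. The strain by region interaction passed the test for 2478 of 8460 probe sets (29.3%), and for 1236 with the scan day as a block. Gnb1 (F = 15.0, adjusted p = 2.19e-13) was lower in C57BL/6J by 2.98 log2 units in the hippocampus, 2.51 in the bed nucleus, 2.44 in the periaqueductal gray and 2.18 in the hypothalamus. In the amygdala and the cingulate cortex the same gene differed by only -0.35 and -0.02 from the mean of the region. Its intensity there was low in every strain (70.4 to 113), against 325 to 672 in the other 5 strains of the 4 brain regions labelled in 1 round, and region and labelling cannot be separated for this loss. Psat1, an enzyme of serine synthesis (F = 21.9, adjusted p = 1.21e-16), differed between strains in the pituitary gland, at -1.85 in C57BL/6J and -1.53 in 129S6/SvEvTac against 0.91 in A/J.

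Pcbp2 and Rnf14 varied by strain mostly in the twice-amplified regions. The amygdala and cingulate cortex were the only regions labelled in 2 rounds. Region and labelling thus cannot be separated for Pcbp2, Rnf14 or Norad there. Pcbp2, an RNA-binding protein (F = 16.7, adjusted p = 3.06e-14), was higher in 129S6/SvEvTac by 1.23 in the amygdala and 1.25 in the cingulate cortex, and in C57BL/6J by 1.06 and 0.94. Rnf14, a ubiquitin ligase (F = 14.8, adjusted p = 2.7e-13), was higher in C3H/HeJ by 1.19 and 1.41 there, and in FVB/NJ by 1.07 and 1.16. Norad, a noncoding RNA that binds Pumilio proteins (F = 18.6, adjusted p = 3.58e-15), was lower in these regions in A/J (-1.20 and -0.84), C57BL/6J (-0.49 and -1.05) and DBA/2J (-0.69 and -0.57). Norad also varied elsewhere, as in the periaqueductal gray, at 0.54 in A/J and -0.63 in C3H/HeJ. The 5 genes with the steepest dependence, apart from Psat1, were Capzb (F = 37.5, adjusted p = 2.59e-21), Gdpd3 (F = 34.7, adjusted p = 7.92e-21), Pdxdc1 (F = 31.5, adjusted p = 5.19e-20), Gas5 (F = 23.3, adjusted p = 4.01e-17) and Pla2g12a (F = 19.6, adjusted p = 1.18e-15). Much of their dependence was tied to the pituitary arrays labelled C3H/HeJ and FVB/NJ. Without those 4 arrays the F values were 7.03, 3.86, 2.56, 2.06 and 1.23 (adjusted p = 7.75e-07, 8.36e-04, 0.0175, 0.0544 and 0.357), so Capzb, Gdpd3 and Pdxdc1 still passed, and 1956 probe sets passed in place of 2478.

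Within single regions the hypothalamus had the most strain differences and the cingulate cortex the fewest. The numbers were 1549 in the hypothalamus, 888 in the pituitary gland, 849 in the periaqueductal gray, 558 in the bed nucleus, 496 in the amygdala, 395 in the hippocampus and 227 in the cingulate cortex. The order rests on single arrays: leaving out 1 array gave 451 to 1535 in the hypothalamus and 447 to 1570 in the periaqueductal gray. With the scan day as a block the counts in the hypothalamus, periaqueductal gray, bed nucleus and amygdala were 870, 245, 298 and 160. In the pituitary gland a fit without the 4 arrays labelled C3H/HeJ and FVB/NJ gave 335. Only 70 probe sets passed in all 7 regions, while 1804 passed in 1 region alone and 5674 in none. A fit within 1 region has few arrays, and in the hippocampus it recovered 3 of 100 simulated changes of 1.5-fold. Passing in 1 region alone thus does not show that a difference is confined to that region.

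The bed nucleus of the stria terminalis (13 arrays against 36) had 50 probe sets at least 2-fold higher and 18 lower than the mean of the hippocampus, hypothalamus and periaqueductal gray. By the naming rule all named genes here and in the next comparisons had the same sign in 6 of 6 strains. The protein kinase gene Prkcd was 10.5-fold higher (3.39 ± 0.09, SE) at 1277 against 108. Ttr, the thyroid hormone carrier made by the choroid plexus, was higher by 3.71 ± 0.37 log2 units at 886 against 53.2. The homeobox gene Shox2 was 9.43-fold higher (3.24 ± 0.08), oxytocin (Oxt) 8.90-fold (3.15 ± 0.07) and vasopressin (Avp) 7.02-fold (2.81 ± 0.13). Zic1 (2.87 ± 0.16), Ramp3 (2.68 ± 0.10), the GABA-A receptor subunit gene Gabrd (2.46 ± 0.10), hypocretin or Hcrt (2.28 ± 0.15) and Rora (2.08 ± 0.09) followed. Adjusted p for these 10 genes ranged from 4.08e-29 to 3.85e-10. The hypothalamus, a region in the comparison, was higher still in Oxt, Avp and Hcrt. Their intensities there were 3458, 4098 and 985, against 2526, 742 and 694 in the bed nucleus. Ttr varied from 25.0 to 4350 between arrays of this region. The count fell from 68 to 25 without replicate 1 of each group.

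Genes of the subpallium marked this region: 13 of 14 were higher and none lower (13 adjusted over the list alone; median 0.68, adjusted p = 2.77e-19), with Dlx1 (1.62 ± 0.07), Six3 (1.60) and Dlx2 (1.18). Amygdala genes were higher for 8 and lower for 4 of 12 (8 and 4 adjusted over the list alone; median 0.66, adjusted p = 7.93e-04). Choroid plexus genes were all higher, 6 of 6 (6 adjusted over the list alone; median 1.44, adjusted p = 2.09e-07 and adjusted p = 0.0616 with an estimated correlation), with Folr1 (1.61) and Kl (1.55). Myelin genes were higher for 8 of 9 (8 adjusted over the list alone; median 0.39, adjusted p = 8.39e-05 and adjusted p = 0.165 with an estimated correlation), with Mobp at 0.54. Higher as well were hypothalamic genes (9 higher and 3 lower of 20, 10 and 4 adjusted over the list alone; adjusted p = 0.00737 and adjusted p = 0.162 with an estimated correlation), genes of GABA interneurons (7 and 4 of 14, 8 and 4 adjusted over the list alone; adjusted p = 0.0199 and adjusted p = 0.0652 with an estimated correlation) and GABA-A receptor genes (3 and 1 of 7, 4 and 1 adjusted over the list alone; adjusted p = 0.0224 and adjusted p = 0.117 with an estimated correlation).

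Midbrain genes were lower in the bed nucleus (9 of 14 lower and 2 higher, 9 and 2 adjusted over the list alone; median -0.47, adjusted p = 2.67e-06), as were hippocampus genes (8 of 12 lower and 3 higher, 8 and 3 adjusted over the list alone; median -0.38, adjusted p = 3.44e-04). Astrocyte genes were lower for 4 of 13 (6 adjusted over the list alone; adjusted p = 0.00444 and adjusted p = 0.0567 with an estimated correlation), led by Gfap (-0.83). Ependymal genes were lower for 2 of 5 (2 adjusted over the list alone; adjusted p = 0.0206 and adjusted p = 0.162 with an estimated correlation). Meningeal genes were lower for 8 and higher for 1 of 14 (9 and 2 adjusted over the list alone; adjusted p = 0.00212 and adjusted p = 0.292 with an estimated correlation). Cortical glutamatergic genes (5 of 11 lower and 2 higher, 5 and 2 adjusted over the list alone; adjusted p = 0.00464 and adjusted p = 0.056 with an estimated correlation), histocompatibility genes (5 of 18 lower, 7 adjusted over the list alone; adjusted p = 0.0358 and adjusted p = 0.256 with an estimated correlation), monoamine genes (4 of 13 lower and 1 higher, 4 and 2 adjusted over the list alone; adjusted p = 0.0459 and adjusted p = 0.199 with an estimated correlation) and ribosomal genes (2 of 15 lower, 0 adjusted over the list alone; adjusted p = 0.0496 and adjusted p = 0.42 with an estimated correlation) were lower too.

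**Figure D4:**
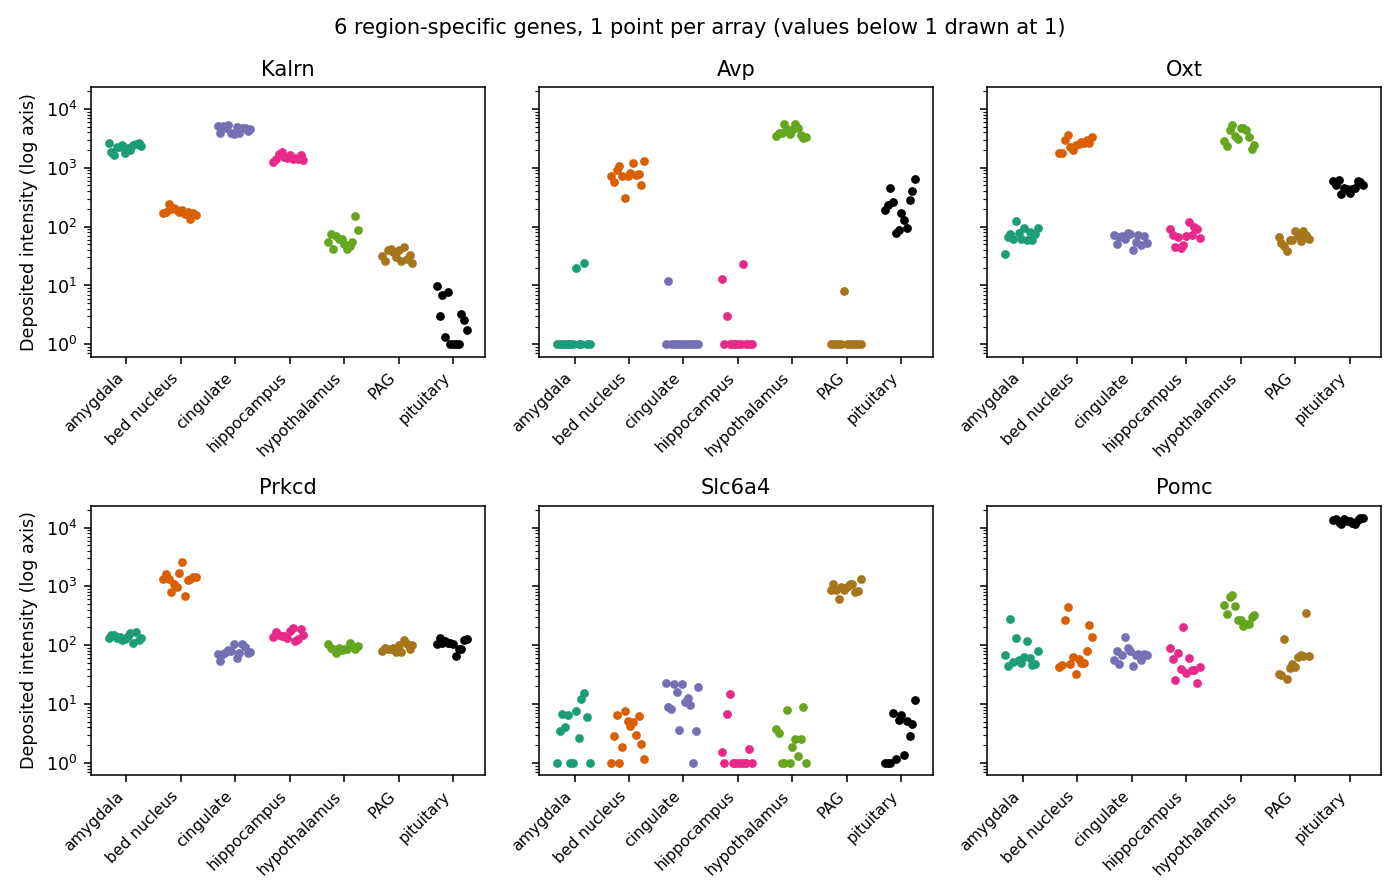
Intensity of Kalrn, Avp, Oxt, Prkcd, Slc6a4 and Pomc (vertical axis, logarithmic) by region (horizontal axis). Each point is 1 array.

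The hippocampus (12 arrays against 37) differed most among the 4 brain regions labelled in 1 round, with 201 probe sets higher and 139 lower by 2-fold. Kalrn was 16.8-fold higher (4.07 ± 0.07, SE) at an intensity of 1510. The transcription factor genes Neurod6 (15.8-fold, 3.98 ± 0.08), Neurod2 (3.63 ± 0.12) and Tbr1 (3.49 ± 0.10) mark forebrain excitatory neurons and were higher. Crym, a thyroid hormone binding protein, was 16-fold higher. Ptk2b, a calcium-regulated kinase (3.44 ± 0.06), lipoprotein lipase or Lpl (3.33 ± 0.09), neurogranin or Nrgn (3.22 ± 0.10), the recycling motor Myo5b (3.01 ± 0.07) and cholecystokinin or Cck (2.89 ± 0.08) were higher, with adjusted p from 1.21e-33 to 3.03e-25 for the 10 genes. Other probe sets of Kalrn, Lpl and Myo5b read 0.50, 2.17 and 0.74, so the size of a difference depends on the probe set. Counting any size of effect, 2054 probe sets were higher and 2531 lower.

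Hippocampus genes were higher for 11 of 12 and lower for 1 (11 and 1 adjusted over the list alone; median 1.42, adjusted p = 1.68e-09), among them Nptx1 (2.33) and Dsp (2.14). Cortical glutamatergic genes were higher for 9 of 11 and lower for 1 (9 and 1 adjusted over the list alone; median 2.24, adjusted p = 2.09e-07). Glutamate receptor genes were higher for 7 of 10 and lower for 3 (7 and 3 adjusted over the list alone; median 0.52, adjusted p = 0.0337 and adjusted p = 0.0772 with an estimated correlation), with Gria1 (1.33) and Gria2 (1.14). The activity-dependent immediate early genes Nr4a1 (1.74), Dusp6 (1.30) and Egr1 (1.18) were higher, and their list was called with 11 of 16 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.00432 and adjusted p = 0.318 with an estimated correlation). Microglia genes were higher for 9 of 11 (9 adjusted over the list alone; adjusted p = 0.0135 and adjusted p = 0.107 with an estimated correlation), with C1qb at 0.48.

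Hypothalamic genes were lower in the hippocampus for 17 of 20 (17 adjusted over the list alone; median -1.05, adjusted p = 4.73e-08). Midbrain genes (11 of 14 lower, 11 adjusted over the list alone; adjusted p = 4.64e-05) and subpallial genes (9 of 14 lower and 1 higher, 9 and 1 adjusted over the list alone; adjusted p = 0.00413) were lower too. Glyoxalase and antioxidant genes were lower for 14 of 29 (14 adjusted over the list alone; median -0.11, adjusted p = 0.0165 and adjusted p = 0.0583 with an estimated correlation), led by the secreted glutathione peroxidase gene Gpx3 (-3.68). Ependymal genes were lower for 4 of 5 (4 adjusted over the list alone; adjusted p = 0.0168 and adjusted p = 0.145 with an estimated correlation).

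In the hypothalamus (12 arrays against 37) neuropeptide genes had the largest differences, and 66 probe sets were higher and 36 lower by 2-fold. Avp was 67.0-fold higher (6.07 ± 0.13, SE) at 4098 against 45.4. Oxt was 13.5-fold higher (3.75 ± 0.07), and Hcrt, the wake-promoting peptide of the lateral hypothalamus, 7.67-fold (2.94 ± 0.15). The histamine-producing enzyme Hdc (2.36 ± 0.09), Gpx3 (2.36 ± 0.06), Sytl4 (2.32 ± 0.10), proopiomelanocortin or Pomc (2.13 ± 0.16), the peptide PACAP or Adcyap1 (2.09 ± 0.08), Magel2 of the Prader-Willi region (2.08 ± 0.09) and fibromodulin or Fmod (1.78 ± 0.14) followed. Adjusted p for the 10 genes ranged from 1.77e-31 to 5.67e-13.

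All 20 hypothalamic genes were higher (20 adjusted over the list alone; median 1.27, adjusted p = 3.09e-21). Pituitary genes were higher for 11 of 18 and lower for 1 (12 and 1 adjusted over the list alone; median 0.40, adjusted p = 8.38e-05), with Cga (1.78) and Tshb (1.25). Genes of tissues that border the hypothalamus moved with it: meningeal genes for 11 of 14 (11 adjusted over the list alone; adjusted p = 9.3e-05 and adjusted p = 0.162 with an estimated correlation) with Ptgds (1.26) and Igf2 (1.25), and ependymal genes for 4 of 5 (4 adjusted over the list alone; adjusted p = 0.00228 and adjusted p = 0.0583 with an estimated correlation). Histocompatibility genes were higher for 10 of 18 (12 adjusted over the list alone; adjusted p = 8.8e-04 and adjusted p = 0.0583 with an estimated correlation), with H2-Q1 at 0.74. Subpallial genes (9 of 14 higher and 3 lower, 9 and 4 adjusted over the list alone; adjusted p = 0.0057 and adjusted p = 0.056 with an estimated correlation) and ribosomal genes (11 of 15 higher and 1 lower, 11 and 1 adjusted over the list alone; adjusted p = 0.0354 and adjusted p = 0.387 with an estimated correlation) were also higher.

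Lower in the hypothalamus were cortical glutamatergic genes (10 of 11, 10 lower and 1 higher adjusted over the list alone; median -0.54, adjusted p = 2.02e-05), with Tbr1 at -1.16, and hippocampus genes (8 of 12 lower and 2 higher, 8 and 2 adjusted over the list alone; adjusted p = 5.96e-04). Mitochondrial genes were lower for 15 of 27 (16 adjusted over the list alone; adjusted p = 1.02e-05 and adjusted p = 0.108 with an estimated correlation). Myelin genes were lower for 8 of 9 (8 adjusted over the list alone; adjusted p = 8.83e-05 and adjusted p = 0.165 with an estimated correlation), with Mag at -0.85.

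The periaqueductal gray (12 arrays against 37) had 37 probe sets higher and 78 lower by 2-fold. The serotonin transporter gene Slc6a4, a marker of raphe neurons, was 51.3-fold higher (5.68 ± 0.07, SE) at 934 against 2.52. The midbrain transcription factor genes En1 (10.6-fold, 3.41 ± 0.10), Gata3 (3.26 ± 0.10) and Tal1 (2.00 ± 0.07) were higher, as was Ddc (2.72 ± 0.08), the enzyme that makes dopamine and serotonin. The vesicle genes Vamp1 (2.91 ± 0.16) and Syt2 (2.33 ± 0.08), gamma-synuclein or Sncg (1.91 ± 0.08), the homeobox gene Irx3 (1.86 ± 0.08) and the oligodendrocyte protease gene Klk6 (1.81 ± 0.13) followed, with adjusted p from 4.20e-37 to 1.60e-14 for the 10 genes. Other probe sets of Slc6a4, Vamp1, Syt2 and Sncg had smaller differences, at 1.28, 0.88, 0.97 and 1.29.

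Midbrain genes were higher for 11 of 14 and lower for 1 (12 and 1 adjusted over the list alone; median 1.18, adjusted p = 2.76e-13). Monoamine genes were higher for 7 of 13 (7 adjusted over the list alone; median 0.37, adjusted p = 8.69e-04), with tyrosine hydroxylase or Th (1.03) and the dopamine transporter gene Slc6a3 (1.02). Mitochondrial genes were higher for 22 of 27 and lower for 1 (24 and 1 adjusted over the list alone; median 0.24, adjusted p = 3.55e-08), with Ndufb5 at 0.44. Glyoxalase and antioxidant genes were higher for 12 of 29 and lower for 1 (12 and 1 adjusted over the list alone; median 0.10, adjusted p = 0.0166 and adjusted p = 0.0583 with an estimated correlation). Astrocyte genes (7 of 13 higher and 1 lower, 7 and 1 adjusted over the list alone; adjusted p = 0.0345 and adjusted p = 0.16 with an estimated correlation), with Aqp4 at 0.62 but Gfap at -1.11, and myelin genes (7 of 9 higher, 9 adjusted over the list alone; adjusted p = 0.00599 and adjusted p = 0.369 with an estimated correlation), with Mag at 0.87, were also higher.

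All 12 hippocampus genes were lower in the periaqueductal gray (12 adjusted over the list alone; median -0.61, adjusted p = 2.75e-09). Cortical glutamatergic genes were lower for 9 of 11 and higher for 2 (9 and 2 adjusted over the list alone; median -1.08, adjusted p = 8.23e-06), with Tbr1 at -2.68. Hypothalamic genes (11 of 20 lower and 2 higher, 12 and 2 adjusted over the list alone; adjusted p = 3.81e-05), with Avp at -4.54, and subpallial genes (9 of 14 lower and 4 higher, 10 and 4 adjusted over the list alone; adjusted p = 0.00142), with Dlx1 at -3.11, were lower. Microglia genes were lower for 10 of 11 (10 adjusted over the list alone; median -0.27, adjusted p = 0.00186), with C1qb at -0.45, and glutamate receptor genes for 8 of 10 with 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.00951). Meningeal genes (12 of 14, 12 adjusted over the list alone; adjusted p = 1.29e-04 and adjusted p = 0.165 with an estimated correlation), immediate early genes (9 of 16 and 1 higher, 11 and 1 adjusted over the list alone; adjusted p = 0.0184 and adjusted p = 0.421 with an estimated correlation) and amygdala genes (8 of 12 and 3 higher, 9 and 3 adjusted over the list alone; adjusted p = 0.0168 and adjusted p = 0.0583 with an estimated correlation) were lower as well.

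The pituitary gland (12 arrays against 49) differed from the 4 brain regions labelled in 1 round in 830 probe sets higher and 910 lower by 2-fold. Its hormone genes were highest: prolactin or Prl 165-fold (7.37 ± 0.29, SE) at 11379 against 53.0, the shared glycoprotein subunit Cga 162-fold (7.34 ± 0.13) and Pomc 109-fold (6.77 ± 0.16). Tshb (6.09 ± 0.11), Lhb (5.89 ± 0.07), Fshb (5.57 ± 0.08) and growth hormone or Gh (5.52 ± 0.45, 14398 against 298) followed. The adrenaline-synthesis gene Pnmt (4.86 ± 0.35), the Notch-like gene Dlk1 (4.78 ± 0.07), the epithelial adhesion gene Epcam (4.31 ± 0.08), Rdh11 (4.10 ± 0.07) and the imprinted gene Mest (4.06 ± 0.08) were higher too. A second probe set of Rdh11 read -0.26 and passed the test in the other direction, and one of Pnmt read -0.02.

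The lowest genes in the pituitary gland were genes of neurons and glia. Gad1, which makes GABA, was 97.1-fold lower (-6.60 ± 0.06) at 2.42 against 1771, and the myelin gene Mobp 75.8-fold lower (-6.24 ± 0.17). Somatostatin (Sst) was at the floor of 0 in the pituitary gland, to which values below 0 were set, against 1030 in the brain regions. The vesicular GABA transporter gene Slc32a1 (-5.64 ± 0.05), visinin-like 1 or Vsnl1 (-5.49 ± 0.06) and angiotensinogen or Agt (-5.12 ± 0.05) were lower. Adjusted p for the 18 named genes ranged from 1.03e-46 to 6.55e-14.

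Pituitary genes were higher for 16 of 18 and lower for 1 (16 and 1 adjusted over the list alone; median 3.88, adjusted p = 9.94e-08). All 18 histocompatibility genes were higher (18 adjusted over the list alone; median 1.86, adjusted p = 2.26e-06), with H2-Aa (3.07), H2-D1 (2.23) and B2m (2.10). Ribosomal genes were higher for 14 of 15 (14 adjusted over the list alone; median 0.60, adjusted p = 5.96e-04 and adjusted p = 0.126 with an estimated correlation), with Rplp0 at 1.37. Lower were astrocyte genes (13 of 13, 13 adjusted over the list alone; median -2.13, adjusted p = 1.69e-07), with Aqp4 at -2.90, genes of GABA interneurons (13 of 14, 13 adjusted over the list alone; median -2.79, adjusted p = 1.1e-06) and glutamate receptor genes (10 of 10, 10 adjusted over the list alone; adjusted p = 0.00142), with Gria1 at -3.22. Myelin genes were lower for 8 of 9 (8 adjusted over the list alone; median -2.84, adjusted p = 2.59e-04 and adjusted p = 0.198 with an estimated correlation), with Mbp at -5.03, and mitochondrial genes for 26 of 27 (26 adjusted over the list alone; median -0.61, adjusted p = 2.72e-07 and adjusted p = 0.0583 with an estimated correlation), with Cycs at -1.47. GABA-A receptor genes (6 of 7, 6 adjusted over the list alone; adjusted p = 0.00834 and adjusted p = 0.0621 with an estimated correlation), microglia genes (10 of 11, 10 adjusted over the list alone; adjusted p = 0.0199 and adjusted p = 0.13 with an estimated correlation) and cortical glutamatergic genes (8 of 11 and 2 higher, 8 and 2 adjusted over the list alone; adjusted p = 0.0465 and adjusted p = 0.173 with an estimated correlation) were lower too. The list of stress and corticotropin-releasing hormone genes was called in none of the 12 comparisons by camera with the preset correlation (lowest adjusted p = 0.137). Pre-ranked camera called it higher in the hypothalamus (adjusted p = 5.98e-04) and lower in the periaqueductal gray (adjusted p = 0.00933). Fkbp5, a glucocorticoid-induced chaperone, was higher in the pituitary gland (1.75).

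The amygdala (13 arrays) had 61 probe sets higher and 73 lower by 2-fold than the cingulate cortex (13 arrays), both amplified in 2 rounds. The thyrotropin-releasing hormone receptor gene Trhr was 8.69-fold higher (3.12 ± 0.21, SE) at 252 against 14.8. The neuropeptide Y receptor gene Npy2r (2.64 ± 0.11), the nuclear receptor gene Nr2f2 (2.52 ± 0.17), Magel2 (2.43 ± 0.12), the homeobox gene Pbx3 (2.39 ± 0.11), proenkephalin or Penk (2.32 ± 0.14), the myosin gene Myh7 (2.29 ± 0.16) and the glutathione transferase gene Gstm6 (2.15 ± 0.17, with a second probe set at -0.10) were higher. Prostaglandin D synthase or Ptgds was 4.56-fold lower (-2.19 ± 0.29). Cd34 (-2.05 ± 0.09), 1110008P14Rik (-1.91 ± 0.11), Npnt (-1.90 ± 0.10), the neuronal transcription factor gene Mef2c (-1.83 ± 0.11), the troponin gene Tnnc1 (-1.80 ± 0.15), parvalbumin or Pvalb (-1.72 ± 0.11) and Dkk3 (-1.72 ± 0.07) were lower in the amygdala. Adjusted p for the 16 genes ranged from 7.94e-12 to 1.62e-05.

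Amygdala genes were higher for 8 of 12 (9 adjusted over the list alone; median 0.43, adjusted p = 1.45e-06), with Zfhx3 (1.29) and Tac2 (1.06). Cortical glutamatergic genes were lower for 8 of 11 (8 lower and 1 higher adjusted over the list alone; median -0.66, adjusted p = 8.23e-06), with Tbr1 at -1.27. Subpallial genes were higher for 9 of 14 and lower for 2 (10 and 2 adjusted over the list alone; median 0.46, adjusted p = 4.4e-04 and adjusted p = 0.0869 with an estimated correlation), with Tac1 (1.73). Hypothalamic genes were higher for 7 of 20 (7 adjusted over the list alone; adjusted p = 6.36e-05 and adjusted p = 0.0583 with an estimated correlation), with Hap1 (1.58) and Ndn (1.18). Choroid plexus genes were higher for 2 of 6 (6 adjusted over the list alone; adjusted p = 0.0129 and adjusted p = 0.397 with an estimated correlation).

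Immediate early genes were lower in the amygdala for 9 of 16 and higher for 1 (11 and 2 adjusted over the list alone; median -0.42, adjusted p = 5.96e-04 and adjusted p = 0.252 with an estimated correlation), with Egr2 (-1.33), Egr1 (-1.31), Nr4a1 (-1.23) and Fos (-1.22). Endothelial genes were lower for 7 of 12 (8 adjusted over the list alone; median -0.40, adjusted p = 4.2e-04 and adjusted p = 0.0813 with an estimated correlation), with Vwf (-1.08) and Cldn5 (-0.63). Meningeal genes (9 of 14, 10 adjusted over the list alone; median -0.57, adjusted p = 2.15e-04 and adjusted p = 0.292 with an estimated correlation) and blood genes (2 of 4, 3 adjusted over the list alone; adjusted p = 0.0357 and adjusted p = 0.333 with an estimated correlation), with Hba-a1 at -1.13, were lower as well.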

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

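The tests of the size of the interaction under the scan day block, of the strain profile, of the genes with the largest F and of other probe sets of the same gene were chosen only after the result was seen.

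A strain by region interaction passed the test for 2478 probe sets, which means that strain differences varied with the region. With the scan day as a random block the number was 1236, below 0.5 times the first. For the 1273 calls lost the median size of the interaction was 0.977 times that without the block and the standard error 1.16 times. With a mean fitted for each group, the block has little room to change the sizes where a group shares 1 scan day. These ratios thus do not tell whether scan days made the differences. In 28 of 42 groups all arrays share a scan day, so scan day and group are partly confounded, and how much of the interaction came from scan days stays open. The F of the 10 named genes stayed past the threshold, with the largest drop in Pcbp2 (16.7 to 9.66). Among arrays labelled in 1 round the number of interaction probe sets was 2132, so the labelling protocol is excluded as the whole cause. Without the pituitary groups labelled C3H/HeJ and FVB/NJ 1956 probe sets still passed, so exchanged labels are excluded as the whole cause. That number lay within the range of the 14 other pairs of pituitary groups (1928 to 2259). Many of those pairs also left out 1 of these 2 groups, and pairs with neither gave 2090 to 2259. The range thus cannot tell whether exchanged labels made a part of the interaction. The 1205 probe sets that passed with and without the block may be biological, but the block cannot exclude scan days for them.

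The labels of 2 pituitary groups bear on the genes with the steepest dependence. All 4 pituitary arrays labelled C3H/HeJ or FVB/NJ correlated best with the other strain of the pair, which is what an exchange of labels or tubes would give. Leaving out these 2 groups lowered the F of 5 of the 10 named genes below 0.5 times its value. Leaving out 4 other pairs of pituitary groups, all of which include the group labelled C3H/HeJ, also did so for 5, so this count cannot tell an exchange of both groups from a change in 1 group. Capzb, Gdpd3, Pdxdc1, Gas5 and Pla2g12a had F values of 7.15, 1.37, 2.61, 1.83 and 1.17 without the pituitary gland. Capzb and Pdxdc1 still passed (adjusted p = 4.07e-06 and 0.0263) and the other 3 did not (0.304, 0.120 and 0.440), so the pituitary gland is not the whole cause for Capzb and Pdxdc1. Leaving out the gland cannot tell exchanged labels from a strain difference of the gland itself.

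Large strain differences could come from a sequence variant under a probe. Of 17 genes called at 2-fold with another tested probe set designed on another sequence, 13 (76.5%, 95% interval 52.7 to 90.4) had the same sign there in the strain of their largest difference. In every strain where they were called 12 had it (70.6%, 46.9 to 86.7), an interval that includes 50%, so whether mismatch is the cause cannot be told. The other probe sets had a smaller median difference, 0.25 against 1.44, and 4 (Pdxdc1, Prdx2, Tulp3 and H2-D1) passed the test in the opposite direction in a strain. Against mismatch of single probe sets, 10 passed in the same direction.

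In the arrays of the bed nucleus, genes of neighbouring tissue were high. The median log2 difference of a thalamus list was 1.25 over the 3 of 14 genes tested (Rgs16 1.59, Tcf7l2 1.25, Lef1 1.10), above the 99.98 percentile of 10000 random lists. The choroid plexus list without Ttr had a median of 1.32 over 5 genes, above the 99.99 percentile. Both are what thalamus and choroid plexus in the dissected tissue would give. Ttr was at 93.9 and 1977 in the A/J arrays and at 4334, 1314 and 25.0 in the C3H/HeJ arrays, as a part that varied between dissections would give. Replicates lay closer in the other strains, such as C57BL/6J (50.4 and 151) and FVB/NJ (4350 and 3394). A strain difference in Ttr would give the contrast of those 2 strains as well. Given the thalamus list, Prkcd and Shox2 may be thalamic in part, and its median of 1.25 does not tell how much. No such test was run for hypothalamic genes. How far Oxt, Avp and Hcrt in these arrays reflect tissue of the hypothalamus is thus not known.

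Groups differed in how far single genes followed the strain. Among the 10 genes with the largest F, Capzb had F = 37.5, Gdpd3 34.7, Pdxdc1 31.5, Gas5 23.3, Psat1 21.9, Pla2g12a 19.6, Norad 18.6, Pcbp2 16.7, Gnb1 15.0 and Rnf14 14.8. Of 41 probe sets named for strain differences or strain variants 31 passed the test of interaction, and with 6 more named for their F alone 37 of 47 did. Those with an F above 5 were the second Pdxdc1 probe set (11.9), Serpina3n (10.7), Glo1 (9.30), 6430706D22Rik (8.02), Ctse (5.45) and Cpsf2 (5.33). Lower values were those of the second Glo1 probe set (4.40), Gabra2 (4.29), Pam (4.09), Cd59a (3.92), Sspn (3.68), Hat1 (3.33), Prdx2 (3.31), Mir686 (3.25) and Ccr6 (3.15). The lowest were those of Gsr (2.98), Casp9 (2.72), Mtm1 (2.69), Fgfr1op2 (2.68), Padi2 (2.51), Snhg6 (2.44), Aldh9a1 (2.40), Lipa (2.35), Itgb1bp1 (2.31), Myo5a (2.18), H2-D1 (2.02) and Nnt (2.01).

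For each of these counts, 1 of 100 splits of the arrays, the real one, gave a count as large. The splits moved single arrays between groups, so they ignored shared animals and shared scan days. For the interaction they also broke up strain differences that hold in all regions. The splits therefore cannot exclude chance for the interaction alone, nor an effect of scan days. The highest count of another split was 7 for differences among strains and 49 for the interaction. For single strains it was 0 in 129S6/SvEvTac, A/J, C3H/HeJ and DBA/2J, 4 in C57BL/6J and 2 in FVB/NJ. For regions it was 2 in the bed nucleus, 1 in the hippocampus, 46 in the hypothalamus, 10 in the periaqueductal gray, 0 in the pituitary gland and 52 in the amygdala. For strain differences within regions it was 15 in the amygdala, 28 in the bed nucleus, 16 in the cingulate cortex, 74 in the hippocampus, 103 in the hypothalamus, 41 in the periaqueductal gray and 29 in the pituitary gland.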

How the results depend on the processing

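No test in this part was chosen only after the result was seen, but several alternatives were chosen after seeing the data and are named as such. Signal over background limits what can be seen: array medians of 42.3 to 66.1 lie close to background, so genes below an intensity of 55.4 in every group were not tested. Where a value moved, the cause was not tested, unless fewer genes or fewer samples explain it.

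All 22 counts stayed within 1.5 times under each of 3 other scalings and under the higher level filter. Named genes that passed the test at first kept their direction in all but 1 alternative. Of 13176 values without single arrays or replicates, 13069 stayed on the same side of the threshold, 107 no longer passed and 0 reversed. These values include some that did not pass at first, whose sign was not followed, and interaction F values, which have no sign. Other scalings kept 172 of 174 (not Gabra2 in A/J and Glo1 in C3H/HeJ), and the scan day as a block kept 170 of 174. With the group means as samples 81 of 90 were kept and 9 not, and among arrays with 1 scan 53 of 75 were kept and 21 not. The 1 reversal was Glo1 in C3H/HeJ, at -0.0169 among arrays with 1 scan. No C57BL/6J array had 1 scan, so that comparison lacks a strain low in Glo1.

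With a pseudocount of 1 the counts were 55 (129S6/SvEvTac), 43 (A/J), 56 (C57BL/6J), 41 (C3H/HeJ), 52 (DBA/2J) and 39 (FVB/NJ), 113 (bed nucleus), 516 (hippocampus), 185 (hypothalamus), 218 (periaqueductal gray), 243 (amygdala) and 147 for strains within the cingulate cortex. With 64 they were 13, 3, 11, 1, 13 and 7 in the strains, 31, 173, 45 and 49 in the brain regions, 1004 in the pituitary gland, 54 in the amygdala, and 769 and 388 for strains within the amygdala and cingulate cortex. Without a level filter, strain differences were 128 within the cingulate cortex, 957 within the hypothalamus and 502 within the periaqueductal gray, where more probe sets share the adjustment.

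At a minimum of 1.5-fold the strains had 102, 73, 105, 54, 80 and 64 calls, the brain regions 198, 893, 356 and 381, the pituitary gland 3352 and the amygdala 440. With no minimum the strains had 1435, 1252, 1696, 604, 941 and 901, the brain regions 1673, 4585, 3476 and 3993, the pituitary gland 6950 and the amygdala 1911. With 1 probe set per gene (fewer genes tested) 129S6/SvEvTac had 17 calls, C57BL/6J 13, C3H/HeJ 8 and DBA/2J 14, and strain differences were 356 within the bed nucleus, 131 within the cingulate cortex, 986 within the hypothalamus, 546 within the periaqueductal gray and 587 within the pituitary gland.

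With a trended robust prior, strain differences were 775 within the amygdala, 435 within the cingulate cortex, 614 within the hippocampus, 1374 within the periaqueductal gray and 1533 within the pituitary gland. Array weights gave 4486 for the interaction, 1754 within the amygdala and 914 within the bed nucleus. Against the other 5 brain regions, across protocols, the bed nucleus had 246 calls, the hypothalamus 275 and the periaqueductal gray 421. Without the pituitary gland FVB/NJ had 30 calls and the interaction 1412. Gene lists called numbered 31 with an estimated correlation and 175 with fry, against 86.

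The replicate number as a block moved 0 of 21 counts by over 1.5 times. With this block the strains had 26, 15, 24, 13, 25 and 18 calls, differences among strains 3344, the interaction 3034, and strain differences within regions 354 (amygdala), 707, 177, 335, 1197, 723 and 622 (pituitary gland). Region counts with the block were 68, 340, 102, 115, 1740 and 134. The numbers do not pair the arrays: same-numbered arrays of a strain correlated at a mean of 0.00111 (-0.384 to 0.292, 252 pairs), and same-numbered arrays of a region at 0.0152. Scan day as a random block (residual correlation 0.376) gave 1856 for differences among strains, 1236 for the interaction, and 160, 298, 870 and 245 within the amygdala, bed nucleus, hypothalamus and periaqueductal gray. Gene lists by pre-ranked camera were called 77 times with and without the scan day block, 75 of them in both.

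Alternatives chosen after seeing the data follow. The cage as a block and the number of scans as a term moved 0 of 14 counts. Chip lot as a block gave 2091 for differences among strains, an additive fit with the scan day as a fixed term 1623, and the 42 group means as samples 1214. Among arrays with 2 scans, which are fewer, differences among strains were 1860 and C3H/HeJ had 8 calls. Among the 26 arrays with 1 scan the counts were 100 (129S6/SvEvTac), 24 (A/J), 25 (C3H/HeJ), 40 (DBA/2J) and 36 (FVB/NJ), with 576 among strains. None of these arrays is of C57BL/6J, so each strain was set against the others without it. Without the 4 pituitary arrays labelled C3H/HeJ and FVB/NJ, strain differences within the pituitary gland were 335.

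Leaving out each array or replicate in turn gave 25 to 28 calls in 129S6/SvEvTac, 12 to 20 in A/J, 22 to 26 in C57BL/6J, 11 to 16 in C3H/HeJ, 23 to 27 in DBA/2J and 16 to 20 in FVB/NJ. In regions it gave 25 to 71 in the bed nucleus, 316 to 354 in the hippocampus, 75 to 111 in the hypothalamus, 94 to 128 in the periaqueductal gray, 1722 to 1761 in the pituitary gland and 122 to 145 in the amygdala. Differences among strains ran from 256 to 3383 and the interaction from 0 to 3043. The lows came with fewer samples, without replicate 1 of each group, where lone arrays are assumed to vary like the others. By limma the interaction then had 243 probe sets at unadjusted p below 0.05. Single arrays left 2984 to 3383 and 2096 to 3008.

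Strain differences within regions depended on single arrays. They ran from 0 to 756 in the amygdala, 0 to 622 in the bed nucleus and 0 to 203 in the cingulate cortex, with 0 without replicate 1 (limma, unadjusted p below 0.05: 316, 583 and 311). In the hippocampus they ran from 206 to 435, in the hypothalamus from 451 to 1549, in the periaqueductal gray from 447 to 1570 and in the pituitary gland from 449 to 888. Single arrays that moved a count by over 1.5 times, by strain and replicate with the count without each, were: in the amygdala 129S6/SvEvTac 1 (756), A/J 2 (284), C57BL/6J 1 and 2 (203, 211), C3H/HeJ 1 and 2 (311, 310), DBA/2J 2 (304), FVB/NJ 1 and 2 (244, 264). In the bed nucleus of the stria terminalis 129S6/SvEvTac 1 and 2 (269, 260), C57BL/6J 1 and 2 (294, 295), DBA/2J 2 (347). In the cingulate cortex 129S6/SvEvTac 1 and 2 (134, 138), DBA/2J 1 and 2 (141, 144), FVB/NJ 1 and 2 (147, 140). In the hippocampus 129S6/SvEvTac 1 and 2 (206, 213), C57BL/6J 1 and 2 (246, 259), FVB/NJ 1 and 2 (238, 241). In the hypothalamus 129S6/SvEvTac 1 and 2 (901, 887), C57BL/6J 1 and 2 (451, 548). In the periaqueductal gray 129S6/SvEvTac 1 and 2 (550, 514), A/J 1 and 2 (545, 547), C57BL/6J 1 and 2 (482, 464), DBA/2J 2 (1570), FVB/NJ 1 and 2 (447, 452). In the pituitary gland C57BL/6J 1 and 2 (573, 493), C3H/HeJ 1 and 2 (495, 449), DBA/2J 1 and 2 (570, 557), FVB/NJ 2 (550).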

Other observations

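The genes named here were chosen after their values were seen, and the test of the strain profile was chosen only after the result was seen.

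Over the 6 brain regions, without the pituitary gland, 18 probe sets differed by 2-fold in C3H/HeJ and 30 in FVB/NJ. In C3H/HeJ a Pdxdc1 probe set was 7.35-fold higher (log2 difference 2.88 ± 0.08, SE), Klk1b22 2.88-fold (1.53 ± 0.12) and Hbegf, a ligand of the epidermal growth factor receptor, 2.45-fold (1.29 ± 0.07). Lower there were another Pdxdc1 probe set (-1.91 ± 0.09), Ergic1 (-1.50 ± 0.09), Strn4 (-1.47 ± 0.10) and Gas5 (-1.46 ± 0.06). In FVB/NJ the phosphodiesterase gene Gdpd3 was 3.32-fold higher (1.73 ± 0.07) and Serpina3n 2.89-fold (1.53 ± 0.07), followed by Gas5 (1.49 ± 0.06) and the heat shock gene Hspa1b (1.40 ± 0.08). Capzb, which caps actin filaments, was 4.70-fold lower in FVB/NJ (-2.23 ± 0.05), with Glg1 (-1.70 ± 0.07), Pla2g12a (-1.57 ± 0.06) and the growth factor gene Fgf1 (-1.48 ± 0.05).

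None of these genes kept its difference in the pituitary arrays with the same label: Hspa1b and Ergic1 were at -0.00013 and 0.04, and the others had the opposite sign. Pdxdc1 was at -2.31 in the pituitary arrays labelled C3H/HeJ and at 3.29 in those labelled FVB/NJ, and Hbegf at -0.85 and 2.31. Gdpd3 was at -1.58 in the pituitary arrays labelled FVB/NJ and at 3.91 in those labelled C3H/HeJ, and Capzb at 0.40 and -2.56. Of the 18 C3H/HeJ probe sets 3 kept their sign in the pituitary arrays labelled C3H/HeJ (median -0.52 in the direction of the other regions) and 18 in those labelled FVB/NJ (1.51). Of the 30 FVB/NJ probe sets 7 kept their sign in the pituitary arrays labelled FVB/NJ (-0.32) and 30 in those labelled C3H/HeJ (1.26).

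The hypothesis tested was that the labels of these 2 pituitary groups were exchanged. All 4 arrays correlated best with the other strain of the pair, and no other array of the 87 correlated best with a strain other than its label. The exchange is consistent with these 4 correlations of 0.841 to 0.888, and whether labels, tubes or animals were exchanged was not tested. The experiment files of 0 arrays name another strain than the label.

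With only the twice-amplified arrays of the amygdala and cingulate cortex, 1050 probe sets differed among strains and 2 had an interaction. Without single regions the interaction ranged from 1412 (pituitary gland) and 1744 (hypothalamus) to 2708 (cingulate cortex).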
